A study of Mus musculus with 6 samples.

How the data were processed

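RNA was measured in mouse bone-marrow-derived macrophages, which are macrophages grown from marrow precursors. Per the labels' protocols, marrow cells of C57BL/6 mice were cultured for 7 days with macrophage colony-stimulating factor at 10 ng/ml in medium with 10% serum. They then received exosomes, small vesicles released by cells, at 100 µg/ml for 12 h. The exosomes came from epithelial cells that had been cyclically stretched for 6 h or had not been stretched. Libraries were made from 1.3 µg of total RNA with a SMARTER mRNA-Seq kit, per the labels' protocols. The source and species of the epithelial cells and the strandedness of the libraries are not given in the sources used here. There were 2 groups of 3 libraries, named here stretched 1 to 3 and static 1 to 3 after the replicate numbers in the titles. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

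The deposited gene table and transcript table hold an estimated count for each feature and library, which is not whole and not normalised, per the file headers. The deposited tables also hold a normalised value without a named unit. It equals the count divided by an effective length and by the library total, so it was read as FPKM made by the authors. The aligner and the counting tool are not given in the sources used here. GRCm38 and mm10 are named as builds in the submitters' processing notes. The authors' group averages and a table that only maps identifiers were not used here. How reads shared between near-identical genes or overlapping genes were divided is not stated, so values of multigene families such as H2-Q7 and the interferon-induced Ifi genes are uncertain in that respect.

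Totals ran from 16984561 to 17625991 estimated counts per library. The 10 most abundant genes took 8.55% to 10.4% of each library. Intervals and sampling noise computed from counts cover counting error only. Of 16906 gene identifiers, 16802 matched the reference annotation of GRCm38.p6 and 16488 had the same symbol there. Coordinates are 1-based and come from that annotation. The table holds 2 entries named Plin2, and the less abundant was kept under its identifier.

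Estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr (minimum count 10), which left 12892 genes for testing and 4014 untested. Stretched and static libraries were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Levels are counts scaled to the TMM-adjusted library total (CPM). The standard error of a log2 fold change was derived from the F statistic. The transcript table was tested in the same way. In a simulation of this comparison over 12892 genes, the test recovered 28 of 100 genes changed 2-fold and 87 of 100 changed 4-fold, with 6 false calls. On the same simulated counts DESeq2 recovered 58 and 98 with 46 false calls, limma on log2 values 28 and 91 with 7, and edgeR with the replicate block 19 and 82 with 11. The counts were drawn with edgeR's own dispersions, so the comparison of tests may favour edgeR. Far fewer genes were changed in the simulation than were called in the data, so these rates may not carry over.

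Gene lists (31, of which 30 had tested members) were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Each list was tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01 on log2 CPM (prior count 2), adjusted over the lists. Camera was run again with an estimated correlation, and fry was run for directional and mixed change. In simulated data camera called the list of 30 genes changed 2-fold and 0 of 30 unchanged lists. The simulated genes were drawn independently, so that run could not test how camera at the preset value behaves where genes are correlated. In the data the estimated correlation ran from -0.026 for matrix and fibrosis genes to 0.79 for mast cell and basophil genes. Intervals of list medians are 95% bootstrap intervals over genes from 10000 draws, and genes are not independent replicates.

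The rule names a panel of 12 genes, because the series title speaks of polarization, Notch2 and Socs1. It adds the 9 largest rises and the 9 largest falls among genes past the threshold whose libraries separated completely and whose mean was at least 5 CPM. From each list it takes up to 3 members with the smallest p past the threshold, or the 2 most abundant where none passed. No gene had to be skipped in the ranking (0 in each direction). Other genes are named only where a count was small or in the closing part, and were then chosen after their values had been seen. A gene that the rule takes from a list is not reported here. Retnla, a panel member, and the mitochondrially encoded genes were not analysed here.

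The replicate numbers appear in the titles alone, so whether they pair the libraries was checked from the data. Deviations from the group means correlated at 0.29 for number 1, 0.18 for number 2 and 0.18 for number 3, and 6 of 6 libraries correlated best with their own number in the other group. These correlations are low, and deviations from a group mean cancel within the group, so the 6 matches are not independent and do not settle the pairing. The main fit leaves the replicate number out. The fit with that number as a block is given where it changes the call of a list or of a named gene. Member counts of lists also moved with the block and are given for some lists only. No library pair was a duplicate. Chi-square per degree of freedom over genes was lowest for static 1 and static 2, at 16.4.

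Alternatives were DESeq2's size factors, upper-quartile factors, library size alone, DESeq2 1.42.0, genes with any count, at least 10 counts in every library, the block, and each library left out in turn. Leaving out stretched 3 and static 3 together, limma on log2(FPKM + 1) for genes with a mean FPKM of at least 1, DESeq2 with each library left out and a list of ribosome biogenesis genes were added after seeing the data. DESeq2 with a library left out was used for counts of genes alone, so ranges over all alternatives leave it out.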

Results

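RNA of macrophages was compared in 6 libraries, 3 from cells given exosomes of stretched epithelial cells and 3 from cells given exosomes of unstretched ones. The totals were 17295476, 17383971 and 17300620 estimated counts in stretched 1 to 3 and 17625991, 17605844 and 16984561 in static 1 to 3. The first principal component held 52.1% of the variance and separated the groups, and the second held 26.2% and set static 3 apart. Static 1 and static 2 correlated at 0.991 across genes (log2 CPM), and static 3 correlated with them at 0.95 and 0.954. In static 3 the neutrophil markers lay above the other static libraries by a median of 1.35 on the log2 scale (16 of 16 genes), and the monocyte markers by 1.63 (11 of 11 genes). Markers of mast cells, lymphocytes, stroma, dendritic cells and lung epithelium were higher there too, by medians of 1.19, 0.909, 0.717, 0.594 and 0.54. There was no group without exosomes, so every value is relative to exosomes of unstretched cells.

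The comparison asks how stretching the donor cells alters the response of macrophages to their exosomes. With exosomes of stretched cells, 844 genes were higher and 694 lower of 12892 tested (adjusted p under 0.05, edgeR quasi-likelihood test), and 513 and 281 of them by at least 2-fold. Nos2, the inducible nitric oxide synthase, rose most, and the cytokine genes Il6 and Ccl5 and the arginase gene Arg1 rose with it. Among the largest falls were Rapgef5, Slc9a9 and Tsr1. All 1538 called genes separated the groups completely, as did 36.7% of all tested genes, where chance gives 10% on average over splits. A gene called with 3 libraries per group separates almost by construction. Genes are also not independent, so neither share weighs against chance. The share of called genes that were higher was 54.9%, against 30% when libraries were scaled by size alone, which shifted the median of all genes to -0.19 on the log2 scale. With the replicate number as a block, 755 genes were higher and 408 lower. The count depended on each library. It was 161 without stretched 1, 36 without stretched 2, 814 without stretched 3, 88 without static 1, 0 without static 2 and 4106 without static 3. Without static 2, 2855 genes had an unadjusted p under 0.05 in edgeR, the smallest adjusted p was 0.0516, and DESeq2 called 1301 genes. DESeq2 called 1629, 1270, 2304, 1288, 1301 and 4501 genes with each library left out in that order. In data simulated for all 6 libraries with edgeR's own dispersions it made 46 false calls where edgeR made 6, and fits with a library left out were not simulated. In the paragraphs that follow, counts with 1 library left out are given in this same order of libraries. Where such a count was 0 in edgeR, the number at an unadjusted p under 0.05 in those same fits follows, and DESeq2 counts are those with all libraries.

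Of the panel, 11 genes were tested and 5 rose, or 7 adjusted over the list alone. Nos2 (gene identifier 18126, chromosome 11, 78920787 to 78960226) averaged 3066 ± 2465 CPM with exosomes of stretched cells and 16.2 ± 12.2 CPM with those of unstretched cells (SD, n = 3), a log2 fold change of 7.57 ± 0.88 (SE, adjusted p = 0.0122). Il6 (gene identifier 16193, chromosome 5, 30013114 to 30019975) rose from 3.20 ± 1.94 to 45.1 ± 10.1 CPM, by 3.81 ± 0.49 (adjusted p = 0.0145). Socs1 (gene identifier 12703, chromosome 16, 10783808 to 10785536), a feedback inhibitor of cytokine signalling, rose from 14.3 ± 2.78 to 55.3 ± 6.66 CPM, by 1.95 ± 0.18 (adjusted p = 0.011). Arg1 (gene identifier 11846, chromosome 10, 24915207 to 24927470), a marker of alternative activation, rose by 4.85 ± 1.2 (adjusted p = 0.0433, and 0.0859 with the replicate block; 0.00372 to 0.142 over all alternatives), with static libraries at 35.3, 13 and 0.479 CPM and stretched libraries at 191, 429 and 790 CPM. Il10, which encodes an anti-inflammatory cytokine, rose by 1.28 ± 0.32 (adjusted p = 0.0447). Notch2 (gene identifier 18129, chromosome 3, 98013538 to 98150367) did not pass, at 249 ± 75.2 against 172 ± 52.7 CPM and a log2 fold change of 0.53 ± 0.29 (adjusted p = 0.243). Its 3 stretched libraries held 250, 324 and 173 CPM and static 3 held 233 CPM. Chil3 and Mrc1, markers of alternative activation, also did not pass, at 0.17 (adjusted p = 0.804) and -0.42 (adjusted p = 0.192). Neither did Tnf at 1.04 (adjusted p = 0.287), Il1b at 1.06 (adjusted p = 0.0893) and Cd86 at 1.19 (adjusted p = 0.0646). The number of panel genes past the threshold was 3, 2, 5, 3, 0 and 6 with each library left out, where edgeR gave 7 at an unadjusted p under 0.05 without static 2, and DESeq2 called 7 with all libraries. Without stretched 3, Tnf and Il1b passed (adjusted p = 0.0254 and 0.0455), and Arg1 and Il10 did not (adjusted p = 0.0855 and 0.0754). Cd86 passed without static 3 (adjusted p = 0.0382). Without stretched 2 the log2 fold changes of Notch2, Tnf, Il1b and Cd86 were 0.27, 0.59, 0.60 and 0.68. That of Notch2 was 0.81 without static 3, and that of Mrc1 was -0.22 without static 1. For Chil3 they were 0.35, 0.15, -0.076, -0.097, 0.016 and 0.71 with each library left out in turn. Il6 did not pass without stretched 2 (adjusted p = 0.0652) or static 2 (adjusted p = 0.0541). Arg1 and Il10 did not without stretched 1 (adjusted p = 0.0833 and 0.0989), stretched 2 (0.127 and 0.157) or static 1 (0.0748 and 0.133). Over all alternatives the adjusted p ran from 2.31e-13 to 0.0652 for Il6, 0.00218 to 0.157 for Il10, 0.0027 to 0.668 for Tnf, 0.00928 to 0.26 for Il1b, 0.0115 to 0.184 for Cd86 and 0.00436 to 0.624 for Notch2.

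**Figure D1:**
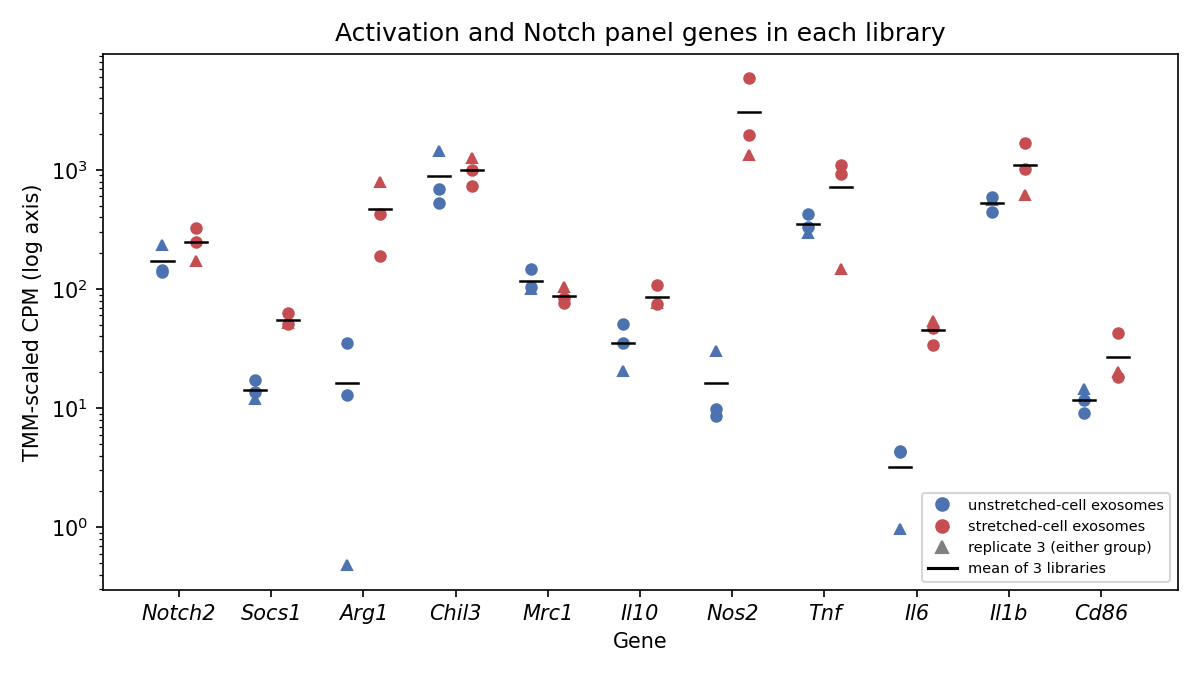
TMM-scaled CPM on a log axis for 11 panel genes in each library, with bars at the mean of 3 libraries per group and triangles for replicate 3. The stretched libraries lie above the static ones for Nos2, Il6, Socs1, Arg1 and Il10, and also for Il1b and Cd86, which did not pass the threshold. Notch2 in static 3 (233 CPM) lies above stretched 3 (173 CPM).

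Besides Nos2 and Arg1, the 9 largest rises held Fcrlb (5.17 ± 0.37, adjusted p = 0.00958), the kinase gene Wnk2 (4.80 ± 0.63), the incretin receptor gene Gipr (4.63 ± 0.49), the chemokine gene Ccl5 (4.57 ± 0.62), the protease gene Mmp10 (4.23 ± 0.58), the prostaglandin synthase gene Ptgs2 (4.03 ± 0.63) and the endothelin receptor gene Ednrb (3.98 ± 0.58), on the log2 scale with SE. Ccl5 (chromosome 11, 83525778 to 83530518) reached 1677 ± 948 CPM from 70.5 ± 37.7 CPM (SD, n = 3). The largest falls were Rapgef5 (-2.95 ± 0.60, adjusted p = 0.0279), Slc9a9 (-2.51), Fgd2 (-2.48), Sco2 (-2.37), the proton-sensing receptor gene Gpr65 (-2.26), the complement regulator gene Cd55 (-2.25), Fcrls (-2.23), the ribosome assembly gene Tsr1 (-2.08) and Slamf9 (-2.08). Rapgef5 (chromosome 12, 117516526 to 117759737) went from 160 ± 104 to 20.6 ± 4.98 CPM, and static 3 held 40.0 CPM. Of all 71 named genes that passed, 27, 6, 48, 14, 0 and 71 passed with each library left out, and 71 of 71 kept their sign in each case. The libraries of these genes separated completely, so the kept sign was all but fixed in advance and is no support. Without static 2 their highest adjusted p was 0.155, and over all alternatives Nos2 ranged from 1.12e-13 to 0.0541.

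Classical activation genes rose as a group, with 9 of 22 tested members higher, 0 lower and 13 not past the threshold (median log2 fold change 1.43, interval 1.04 to 2.04, camera adjusted p = 5.71e-06). The call did not hold with an estimated correlation (adjusted p = 0.627 with an estimated correlation). Nos2, Il6 and Ccl5 led the list. Adjusted over the list alone, 16 members were higher and 1 lower. With each library left out, 4, 1, 13, 3, 0 and 13 members were higher. The 0 compares with 15 at an unadjusted p under 0.05, and DESeq2 called 15. The list passed camera without static 2 (adjusted p = 4.93e-07; 9.18e-08 to 0.627 over all alternatives). NF-kB response genes were called too, with 6 of 29 members higher (median 0.55, adjusted p = 0.00261; adjusted p = 0.768 with an estimated correlation), and 6 adjusted over the list alone. Examples were Ier3 (1.58 ± 0.17) and the neutrophil chemoattractant genes Cxcl2 (2.45 ± 0.32) and Cxcl1 (2.97 ± 0.46). Their number was 4, 1, 9, 1, 0 and 9 with each library left out (10 at an unadjusted p under 0.05 without static 2, and 7 by DESeq2). Chemokines and receptors had 5 higher and 1 lower (Cx3cr1) of 24 (median 0.58, adjusted p = 0.0244; adjusted p = 0.652 with an estimated correlation), and 7 higher and 2 lower adjusted over the list alone. Higher chemokine members numbered 4, 1, 5, 1, 0 and 9 (8 at an unadjusted p under 0.05 without static 2, and 8 by DESeq2). Lower ones numbered 0, 0, 0, 0, 0 and 5, with 2 to 4 at an unadjusted p under 0.05 and 2 by DESeq2. That list was not called without stretched 2 (adjusted p = 0.0814) or static 3 (adjusted p = 0.365), and its range over all alternatives was 0.00572 to 0.652. Without stretched 2 the median was 0.30 for NF-kB response genes and 0.23 for chemokines and receptors.

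Alternative activation genes were not called as a list (adjusted p = 0.0516; adjusted p = 0.652 with an estimated correlation), although 7 of 20 tested members rose and 1 fell (8 and 2 adjusted over the list alone). Vegfa rose from 147 ± 62.6 to 470 ± 74.0 CPM (1.68 ± 0.30), Pdcd1lg2, a ligand of an inhibitory T-cell receptor, rose by 1.89 ± 0.33, and Pparg, a lipid-sensing nuclear receptor gene, fell by 1.41 (SE 0.164). The median was 0.75 with an interval from -0.11 to 1.25. The list was called with the replicate block (adjusted p = 0.015) and with DESeq2's size factors (adjusted p = 0.0476). It was also called without stretched 3, static 1 or static 2 (adjusted p = 0.0432, 0.0351 and 0.0326), and without stretched 3 and static 3 together (adjusted p = 0.031). The range over all alternatives was 0.015 to 0.652. Rising members numbered 0, 0, 3, 0, 0 and 9 with each library left out (7 to 9 at an unadjusted p under 0.05, and 8 by DESeq2). Falling members numbered 1, 0, 1, 1, 0 and 3 (3 to 4 at an unadjusted p under 0.05, and 2 by DESeq2). Of 35 Notch pathway genes, Numbl (0.95 ± 0.14) and Dtx2 (1.08 ± 0.26) rose and Lfng, a glycosyltransferase that modifies Notch receptors, fell by 1.27 (SE 0.272), and 32 did not pass. The same 2 and 1 passed adjusted over the list alone. This list was not called (adjusted p = 0.105; adjusted p = 0.768 with an estimated correlation). It passed without stretched 3 (adjusted p = 0.00854), without static 1 (adjusted p = 0.048) and without stretched 3 and static 3 together (adjusted p = 0.0239). Its range over all alternatives was 0.00854 to 0.768. With the replicate block 4 Notch members rose. With each library left out 0, 0, 2, 0, 0 and 7 were higher (4 to 7 at an unadjusted p under 0.05, and 5 by DESeq2) and 0, 0, 1, 0, 0 and 1 lower (1 at an unadjusted p under 0.05 in each, and 1 by DESeq2).

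SOCS, JAK and STAT genes were higher as a list (6 of 25 higher, 1 lower, median 0.39, adjusted p = 0.00221; adjusted p = 0.682 with an estimated correlation), or 9 and 1 adjusted over the list alone. Socs1 led, followed by Socs3 (288 ± 43.6 to 857 ± 278 CPM, 1.57 ± 0.27) and Cish (1.87 ± 0.34), while Ptpn6, a phosphatase gene, fell by 0.79. Members higher numbered 4 with the replicate block and 1, 1, 4, 1, 0 and 11 with each library left out (8 at an unadjusted p under 0.05 without static 2, and 9 by DESeq2). Lower ones numbered 0, 0, 0, 0, 0 and 1 (1 at an unadjusted p under 0.05 in each, and 1 by DESeq2). The median of this list was 0.25 without stretched 2. Type I interferon response genes were higher with 9 of 31 members past the threshold and 0 lower (median 0.71, adjusted p = 1.07e-07; adjusted p = 0.652 with an estimated correlation), and 18 adjusted over the list alone. The antiviral genes Oasl1 (1.82 ± 0.31) and Rsad2 (2.07 ± 0.41) were among them. Ifnb1, the interferon beta gene, was called on 36 counts against 3, a ratio of 13.8 with a counting interval from 4.35 to 69.8. Interferon members past the threshold numbered 2, 0, 1, 0, 0 and 17 (15 to 19 at an unadjusted p under 0.05, and 16 by DESeq2). Antigen presentation had 3 of 21 higher (H2-Q7, Tapbp and Tap1; median 0.62, adjusted p = 0.00214; adjusted p = 0.723 with an estimated correlation), and 5 adjusted over the list alone. Tapbp did not pass with the replicate block (adjusted p = 0.0584; 0.00214 to 0.172 over all alternatives). The antigen presentation count was 0, 0, 0, 0, 0 and 11 with each library left out (4 to 9 at an unadjusted p under 0.05, and 7 by DESeq2), and the median was 0.34 without stretched 2.

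Glycolysis and hypoxia genes rose together, 13 of 28 higher and 0 lower (median 0.76, interval 0.56 to 0.92, adjusted p = 3e-09; adjusted p = 0.627 with an estimated correlation), and 21 adjusted over the list alone. Egln3, an oxygen-sensing hydroxylase gene, rose from 22.3 ± 8.42 to 103 ± 21.6 CPM (2.21 ± 0.31), Ankrd37 by 1.83 ± 0.24 and the mitophagy gene Bnip3 by 1.41 ± 0.20. The count was 7 with the replicate block and 3, 0, 8, 1, 0 and 15 with each library left out (15 to 16 at an unadjusted p under 0.05, and 19 by DESeq2). Oxidative stress response genes also rose, 9 of 25 higher (median 0.79, adjusted p = 3.1e-06; adjusted p = 0.627 with an estimated correlation), and 14 adjusted over the list alone. The antioxidant gene Prdx1 went from 1669 ± 303 to 6044 ± 2101 CPM (1.86 ± 0.32), and Gstm1 (1.5 ± 0.19) and Gclm (1.18 ± 0.19) rose. These numbered 1, 0, 7, 0, 0 and 12 with each library left out (14 to 16 at an unadjusted p under 0.05, and 15 by DESeq2). Lipid handling genes had 6 of 24 higher (median 0.38, adjusted p = 0.0114; adjusted p = 0.652 with an estimated correlation), and 8 higher and 1 lower adjusted over the list alone. The fatty acid binding protein genes Fabp4 (20.6 ± 5.68 to 119 ± 12.8 CPM, 2.53 ± 0.22) and Fabp5 (1.64 ± 0.20) and the cholesterol transporter gene Npc1 (0.85 ± 0.13) led it. With each library left out 2, 1, 5, 1, 0 and 12 were higher (7 at an unadjusted p under 0.05 without static 2, and 7 by DESeq2), and 2 were lower without static 3. The lipid handling median was 0.21 without static 1, 0.18 without static 2 and 0.61 without static 3. Oxidative phosphorylation had 0 of 33 members past the threshold (median -0.14, adjusted p = 0.114; adjusted p = 0.768 with an estimated correlation), 0 adjusted over the list alone, 2 higher and 6 lower at an unadjusted p under 0.05 in edgeR and 2 lower in DESeq2. Atp5b lay at 461 ± 20.2 against 676 ± 118 CPM (adjusted p = 0.0871) and Atp5a1 at 363 ± 13.6 against 448 ± 39.6 CPM (adjusted p = 0.2), and the list passed without stretched 3 (adjusted p = 0.0196; 0.0196 to 0.768 over all alternatives). Without static 3, 4 members rose and 4 fell. The oxidative phosphorylation median was -0.072 without static 1 and -0.22 without static 3. Cholesterol synthesis was not called (median 0.35, adjusted p = 0.125; adjusted p = 0.835 with an estimated correlation). Its 1 riser was Tm7sf2 (1.16 ± 0.29; adjusted p = 0.0526 with the replicate block, 0.00503 to 0.143 over all alternatives), with 0 adjusted over the list alone, 4 higher at an unadjusted p under 0.05 in edgeR and 3 by DESeq2. Without stretched 3 the list was called (adjusted p = 1.08e-05; 1.08e-05 to 0.934 over all alternatives). Members higher numbered 0, 0, 9, 0, 0 and 2 with each library left out, where the zeros had 2 each at an unadjusted p under 0.05. The cholesterol synthesis median was 0.11 without stretched 1 and 0.55 without stretched 3.

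Lysosome and phagocytosis genes were higher (6 of 33 higher, 1 lower, median 0.39, adjusted p = 0.00221; adjusted p = 0.652 with an estimated correlation), or 10 and 2 adjusted over the list alone. The galactosidase gene Gla (1.60 ± 0.21) and the Fc receptor genes Fcgr2b (1.78 ± 0.33) and Fcgr3 (0.95 ± 0.20) rose and the scavenger receptor gene Stab1 fell by 1.37. The lysosome median was 0.24 without stretched 2. Matrix and fibrosis genes had 4 of 29 higher (median 0.38, adjusted p = 0.0051; adjusted p = 0.627 with an estimated correlation), and 7 higher and 1 lower adjusted over the list alone. Spp1, the osteopontin gene, went from 2378 ± 124 to 6045 ± 1388 CPM (1.35 ± 0.25), and Timp3 (0.95 ± 0.18) and the thrombospondin gene Thbs1 (1.87 ± 0.45) rose. With the replicate block 6 matrix members were higher. Immediate early genes had 7 of 25 higher and 1 lower (median 0.49, adjusted p = 0.00851; adjusted p = 0.627 with an estimated correlation), or 8 and 2 adjusted over the list alone. Ier3, Fosl1 (1.88 ± 0.25) and Nr4a1 (1.45 ± 0.21) led, and Ier2 fell by 0.58 (adjusted p = 0.064 with the replicate block, 0.00366 to 0.142 over all alternatives). With each library left out, lysosome members higher numbered 1, 0, 2, 0, 0 and 9, matrix members 0, 0, 3, 0, 0 and 10, and immediate early members 3, 0, 6, 2, 0 and 9. The zeros compare with 9 to 12, 8 to 11 and 9 to 10 at an unadjusted p under 0.05, and DESeq2 called 11, 10 and 9. Lower lysosome and immediate early members numbered 0 and 0 in edgeR without any library except static 3, without which there were 1 and 3. Those zeros compare with 2 to 3 in each list at an unadjusted p under 0.05, and DESeq2 called 2 and 2.

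Cell cycle was the 1 list called lower (median -0.30, adjusted p = 0.0257; adjusted p = 0.768 with an estimated correlation), yet its members past the threshold were 2 that rose and 0 that fell of 36, and 1 and 0 adjusted over the list alone. They were E2f1 (0.80 ± 0.12), a transcription factor of S-phase entry, and Ccne1 (0.94 ± 0.22; adjusted p = 0.0587 with the replicate block, 0.00416 to 0.131 over all alternatives), the cyclin E1 gene. At an unadjusted p under 0.05 edgeR gave 8 lower, and DESeq2 called 5 lower. The list was not called without stretched 1 (adjusted p = 0.135), stretched 2 (adjusted p = 0.0717) or static 3 (adjusted p = 0.233), and its range over all alternatives was 0.0023 to 0.768. Its members higher numbered 0, 0, 1, 0, 0 and 3 with each library left out (2 at an unadjusted p under 0.05 in each). Those lower numbered 0, 0, 2, 0, 0 and 6 (3 to 8 at an unadjusted p under 0.05). The unfolded protein response and amino acid stress list was not called (adjusted p = 0.839; adjusted p = 0.879 with an estimated correlation), with 4 higher and 1 lower of 28 and the same numbers adjusted over the list alone. Ddit4 (1.27 ± 0.12), Atf3 (1.53 ± 0.24), Vldlr (0.90 ± 0.16) and the cystine transporter gene Slc7a11 (3.03 ± 0.54) rose, and Herpud1 fell by 0.81. Its median was -0.09 and its mean 0.12, where camera's direction was down. Members higher numbered 2, 1, 3, 1, 0 and 4 with each library left out (4 at an unadjusted p under 0.05 without static 2, and 4 by DESeq2). Members lower numbered 0, 0, 0, 0, 0 and 4 (2 to 5 at an unadjusted p under 0.05, and 3 by DESeq2). Heat shock proteins had 1 of 15 higher (Hspa4l, 1.05 ± 0.20; 2 higher and 3 lower adjusted over the list alone; adjusted p = 0.426 and 0.792 with an estimated correlation), a median of -0.12 and a mean of 0.02, where camera's direction was down. Without stretched 3 it had 2 higher, and without static 3 it had 3 higher and 5 lower. Without any other library edgeR called 0, with 2 higher and 3 lower at an unadjusted p under 0.05, and DESeq2 called 2 and 3. Ribosomal proteins had 0 of 34 past the threshold, 0 adjusted over the list alone, 1 lower at an unadjusted p under 0.05 in edgeR and 0 in DESeq2 (median -0.08; adjusted p = 0.165 and 0.847 with an estimated correlation). Rplp0 lay at 1216 ± 166 against 1328 ± 121 CPM and Rps2 at 722 ± 97.1 against 963 ± 154 CPM, and the list passed without stretched 2 (adjusted p = 0.0199; 0.0199 to 0.855 over all alternatives). With each library left out, the median was -0.084, -0.016, -0.18, -0.036, -0.064 and -0.13 for the unfolded protein response list. It was -0.045, -0.19, -0.19, -0.14, -0.044 and -0.19 for heat shock proteins, and -0.13, -0.16, -0.018, -0.058, -0.15 and -0.060 for ribosomal proteins.

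**Figure D2:**
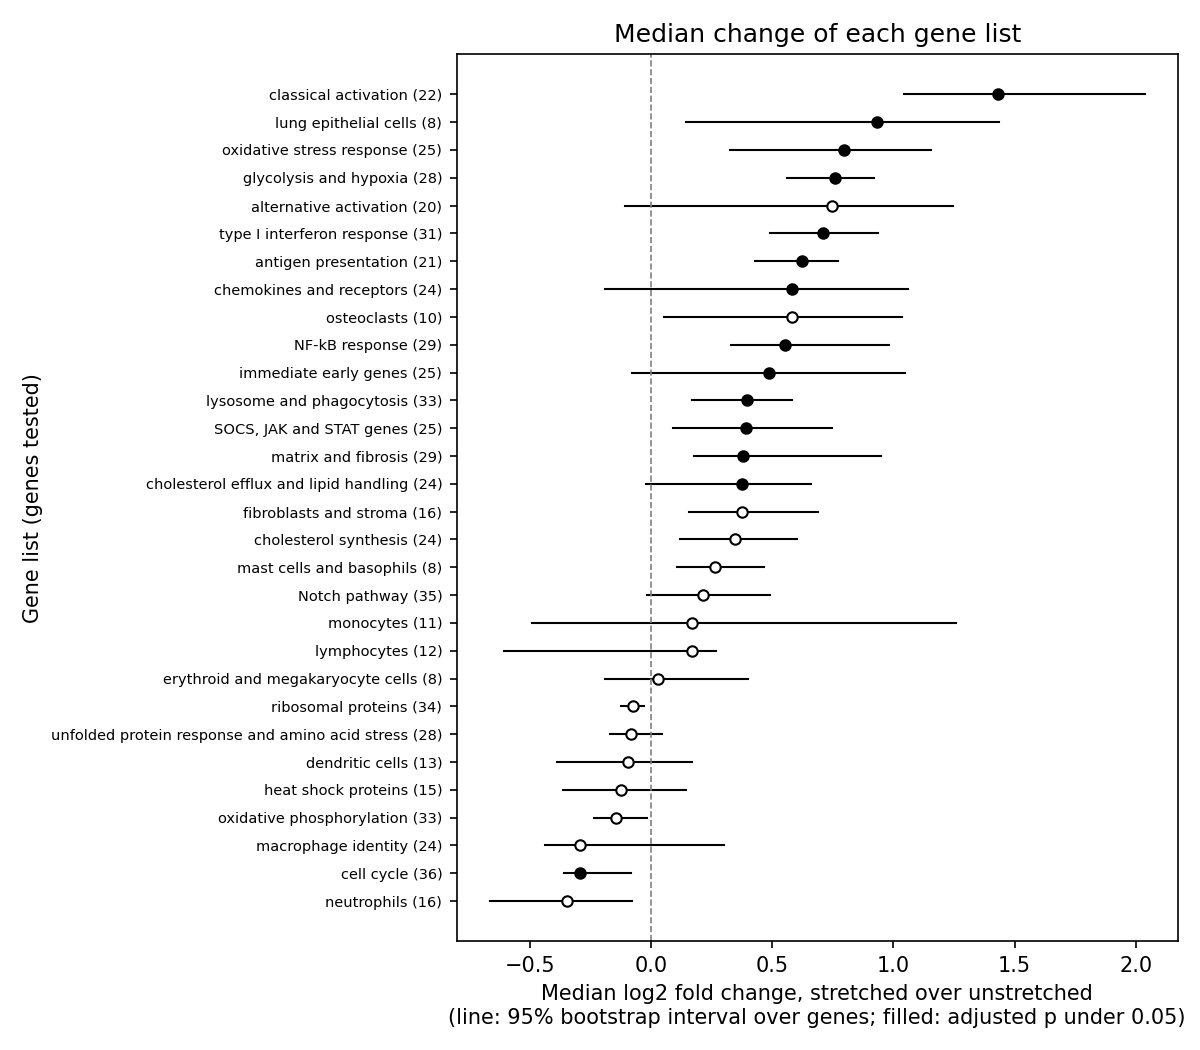
Median log2 fold change of each of 30 gene lists, stretched over static, with 95% bootstrap intervals over genes and the number of genes tested in brackets. Filled points passed camera at the preset correlation (14 lists), and the medians run from -0.35 for neutrophils to 1.43 for classical activation.

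Among macrophage identity genes 2 of 24 rose and 3 fell (3 and 4 adjusted over the list alone), and the list was not called (median -0.29, adjusted p = 0.299; adjusted p = 0.723 with an estimated correlation). Cebpb, a myeloid transcription factor gene, rose from 220 ± 14.2 to 507 ± 113 CPM (1.21 ± 0.20), as did the efferocytosis receptor gene Mertk (adjusted p = 0.056 with the replicate block, 0.00892 to 0.157 over all alternatives). Aif1 fell by 1.03 and the complement gene C1qa by 0.62 (adjusted p = 0.0601 with the replicate block, 1.66e-06 to 0.167 over all alternatives), and the fractalkine receptor gene Cx3cr1 fell by 1.54 (adjusted p = 0.065 with the replicate block, 5.55e-04 to 0.141 over all alternatives). The numbers were 1 and 1 with the replicate block and without stretched 3, and 5 and 5 without static 3. They were 0 and 0 in edgeR without stretched 1, stretched 2, static 1 or static 2, where 2 to 4 were higher and 3 to 5 lower at an unadjusted p under 0.05, and DESeq2 called 5 and 6. The macrophage identity median was -0.19 without static 1 and -0.15 without static 2. Lung epithelial genes were called (3 of 8 higher, median 0.93, adjusted p = 0.0244; adjusted p = 0.652 with an estimated correlation), and 3 adjusted over the list alone. Muc1 held 3.05 ± 1.15 against 0.608 ± 0.309 CPM, Epcam 27.2 ± 12.3 against 10.1 ± 1.76 CPM, and Lcn2, which macrophages also express, 2317 ± 962 against 908 ± 266 CPM. With the replicate block Muc1 and Epcam did not pass (adjusted p = 0.0592 and 0.0605; 5.25e-04 to 0.118 and 0.00191 to 0.154 over all alternatives), and without static 2 the list did not (adjusted p = 0.0552; 0.00843 to 0.652 over all alternatives) and its median was 0.56. Epithelial members higher numbered 1 with the block and 0, 0, 2, 0, 0 and 4 with each library left out (3 to 4 at an unadjusted p under 0.05, and 3 by DESeq2). The epithelial keratin genes Krt7, Krt8, Krt18 and Krt19 averaged 1.97, 0.176, 0.412 and 0.807 CPM in the stretched libraries and 1.09, 0, 0.178 and 0.516 CPM in the static ones, chosen after their values were seen.

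Markers of other cell types mostly did not pass. Neutrophil genes had 0 of 16 called by edgeR, 0 adjusted over the list alone, 1 higher and 2 lower at an unadjusted p under 0.05 and 1 higher in DESeq2 (median -0.35, adjusted p = 0.426; adjusted p = 0.873 with an estimated correlation). Ngp held 2225 ± 515 against 3038 ± 2320 CPM and S100a9 1609 ± 789 against 1812 ± 1178 CPM, with static 3 highest for both (5665 and 3161 CPM). With each library left out the neutrophil median was -0.22, -0.35, -0.67, -0.70, -0.49 and 0.32. In edgeR 1 member was higher without stretched 3 or without static 3, and without static 1 the list was called lower (adjusted p = 0.0351; 0.0351 to 0.996 over all alternatives). Monocyte genes had 1 of 11 higher, Hp (347 ± 241 to 1170 ± 40.1 CPM, 1.75 ± 0.44), and 0 adjusted over the list alone (adjusted p = 0.349 and 0.847 with an estimated correlation), and the list was called without static 3 (adjusted p = 0.00995; 0.00995 to 0.847 over all alternatives) with 5 members higher. Leaving out any of the other libraries ended the call of Hp and left 0 members higher in edgeR (1 to 2 at an unadjusted p under 0.05, and 2 by DESeq2). Dendritic cell genes had 1 of 13 higher, Ccr7 (1.84 ± 0.39), and 1 adjusted over the list alone (adjusted p = 0.799 and 0.933 with an estimated correlation), with a median of -0.10 and a mean of -0.11 where camera's direction was up. Leaving out any library except static 3 ended the call of Ccr7 and left 0 members higher in edgeR (1 to 2 at an unadjusted p under 0.05, and 1 by DESeq2). The dendritic cell median was -0.18, -0.27, -0.14, -0.26, -0.26 and 0.49 with each library left out. Lymphocyte genes had 1 of 12 lower, Ms4a1 (9.01 ± 0.39 to 4.78 ± 0.82 CPM), and 1 adjusted over the list alone (adjusted p = 0.839 and 0.938 with an estimated correlation), with a median of 0.17 and a mean of 0.01 where camera's direction was down. Leaving out any library except static 3 ended the call of Ms4a1 too (1 to 2 lower at an unadjusted p under 0.05, and 1 by DESeq2). Without static 3 another 4 members were higher, and with the block 1 was. The lymphocyte median was 0.015, -0.19, 0.23, -0.14, -0.093 and 0.49 with each library left out. Stroma genes had 0 of 16 called, 0 adjusted over the list alone, 3 higher and 1 lower at an unadjusted p under 0.05 and 2 higher in DESeq2 (median 0.37, adjusted p = 0.0728; adjusted p = 0.768 with an estimated correlation). Col1a1 lay at 2745 ± 392 against 2134 ± 278 CPM and Col1a2 at 1740 ± 166 against 1331 ± 226 CPM, and the stroma list was called with the replicate block (adjusted p = 0.015), without stretched 2 (adjusted p = 0.0189) and without static 3 (adjusted p = 0.00995), with a range of 0.00995 to 0.768 over all alternatives. With the block 3 members were higher, and without static 3 there were 6. The stroma median was 0.22 without static 2 and 0.58 without static 3. Mast cell and basophil genes had 0 of 8 called, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 in edgeR and 0 in DESeq2 (median 0.26, adjusted p = 0.33; adjusted p = 0.835 with an estimated correlation). Hdc and Prss34 had adjusted p = 0.754 and 0.595, and that list was called without static 3 (adjusted p = 0.0178; 0.0178 to 0.955 over all alternatives) with 3 members higher. The mast cell and basophil median was 0.41, 0.092, 0.11, -0.047, 0.093 and 0.84 with each library left out. Osteoclast genes had 0 of 10 called, 3 higher adjusted over the list alone, 3 higher and 1 lower at an unadjusted p under 0.05 in edgeR and 3 higher in DESeq2 (median 0.58, adjusted p = 0.246; adjusted p = 0.768 with an estimated correlation). Mmp9 and Acp5 had adjusted p = 0.89 and 0.161, and the osteoclast list was called without stretched 2 (adjusted p = 0.0166; 0.0166 to 0.823 over all alternatives). With the block 2 osteoclast members were higher, without stretched 3 there was 1, and without static 3 there were 1 higher and 1 lower. Without stretched 3 the osteoclast median was 0.0045. Erythroid and megakaryocyte genes had 0 of 8 called, 0 adjusted over the list alone, 2 higher at an unadjusted p under 0.05 in edgeR and 1 higher in DESeq2 (median 0.03, adjusted p = 0.426; adjusted p = 0.768 with an estimated correlation), with Pf4 and Itga2b at adjusted p = 0.801 and 0.061 and 2 members higher without static 3. The erythroid and megakaryocyte median was 0.043, 0.18, 0.088, 0.068, -0.12 and 0.092 with each library left out.

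Over all lists, camera called 13 higher and 1 lower at the preset correlation and 0 of 30 with an estimated correlation. Fry called 5 lists as moving on balance one way, namely classical activation (adjusted p = 0.0467), glycolysis and hypoxia (0.0437), oxidative stress response (0.043), matrix and fibrosis (0.00133) and immediate early genes (0.0437), and 18 as changing in either direction.

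At transcript level, 29604 of 51947 transcripts were tested and 1 was higher and 0 lower, with 4567 at an unadjusted p under 0.05 in edgeR. It was a predicted transcript of Scaf11, a splicing factor gene, at 763, 532 and 806 estimated counts in stretched 1 to 3 and 0, 1.49 and 0.28 in static 1 to 3 (adjusted p = 0.0358). The Scaf11 gene as a whole was at 93.5 ± 13.3 against 97.8 ± 3.66 CPM (adjusted p = 0.787). With the replicate block 0 transcripts passed in edgeR, and 3706 had an unadjusted p under 0.05. The main Socs1 transcript held 51.4 against 13.6 CPM (adjusted p = 0.0927) and the Notch2 transcript 247 against 174 CPM (adjusted p = 0.518). The 1 call was lost without stretched 1, stretched 2, stretched 3, static 1, static 2 or static 3, each of which left 0 transcripts (3370 to 6367 at an unadjusted p under 0.05).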

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

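Tests chosen after the results were seen were limma on log2(FPKM + 1), leaving out stretched 3 and static 3 together, and DESeq2 with each library left out. Of the 1538 called genes, every one that could be tested kept its direction under each alternative, and of the 14 called lists 14 did. The libraries of all 1538 genes separated completely, so their kept direction was all but fixed in advance and is no support. Calls moved with the library left out. With 1 library left out the count of changed genes ran from 0 to 4106 (higher 0 to 2095, lower 0 to 2011, at least 2-fold 0 to 1606). Panel genes past the threshold ran from 0 to 6 and called lists from 13 to 18, and called transcripts stayed at 0. The count of changed genes rose only without static 3, although each of these fits had the same number of libraries. Scaling by library size alone gave 556 higher and 1297 lower, and limma on log2(FPKM + 1) 529 higher and 1352 lower, both with the median of all genes shifted (-0.19 and -0.17). DESeq2 called 2682 genes (1398 higher, 1284 lower), and in data simulated with edgeR's own dispersions it made 46 false calls against 6 by edgeR. It called 1268 higher without stretched 3, and 4501 (2364 higher, 2137 lower, 1681 at least 2-fold) without static 3. The replicate block gave 408 lower genes and 0 transcripts. Among genes named by the rule the block ended the calls of Arg1, Tm7sf2, Tapbp, Ccne1, Cx3cr1, Muc1 and Epcam, and among genes named after their values were seen those of Actb, C1qa, Ier2 and Mertk. Among lists it added alternative activation and stroma. It changed no other call of the lists fixed beforehand or of the genes named as risen or fallen. Leaving out stretched 3 and static 3 together gave 5355 genes (2700 higher, 2655 lower, 1913 at least 2-fold) and 10 panel genes, Notch2 among them. In that fit camera kept 13 of the 14 called lists and added 8. Those added were alternative activation, Notch pathway, oxidative phosphorylation, cholesterol synthesis, stroma, monocytes, dendritic cells, and mast cells and basophils. An estimated correlation left 0 called lists and fry 5. The cause of these shifts was not tested. Among named genes, the sign changed in uncalled ones alone. Camera's direction turned under some alternatives for uncalled lists (unfolded protein response and amino acid stress, ribosomal proteins, neutrophils, dendritic cells, lymphocytes and mast cells). On the log2 scale, Chil3 was at -0.0295 with library size alone and ran from -0.10 to 0.71 with 1 library left out. The ranges were -0.82 to 0.36 for Ngp, -0.69 to 0.50 for S100a9, -0.074 to 1.15 for Hdc, -0.95 to 0.25 for Mmp9 and -0.59 to 0.25 for Pf4. Without stretched 3 and static 3 together Ngp was at 0.18 and S100a9 at 0.0061, and with the block Pf4 was at 4.8e-04. At this depth and spread, 28 of 100 simulated 2-fold changes were recovered, so missed changes of that size are not shown to be absent.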

Other observations

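The tests in this part were chosen after the results they concern had been seen, except the test of ribosome biogenesis genes as a class, whose prediction was written before the values of its members were seen, on a list added after seeing the data that left out ribosome genes already seen among the largest falls. Genes of ribosome assembly were lower with exosomes of stretched cells. Of 72 genes, 47 fell (65 adjusted over the list alone) and 0 had a log2 fold change above 0, with a median log2 fold change of -1.08 (interval -1.15 to -0.95, camera p = 2.45e-23; p = 0.154 with an estimated correlation, fry p = 0.0173). The RNA polymerase I subunit gene Polr1a went from 46.4 ± 11.6 to 17.2 ± 2.62 CPM (SD, n = 3), and Polr1b, the snoRNP protein gene Nop56 and the methyltransferase gene Fbl fell by 1.55, 1.37 and 1.24. Static 3 lay below the other static libraries by a median of -0.69 on the log2 scale (interval -0.78 to -0.61), and above them for 3 of the 72 genes. Members called lower numbered 29 with the replicate block and 0, 0, 16, 0, 0 and 65 in edgeR without stretched 1, stretched 2, stretched 3, static 1, static 2 and static 3, with medians from -1.3 to -0.916. Where the count was 0, edgeR gave 59 to 61 at an unadjusted p under 0.05 and DESeq2 called 35 to 55.

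Actb, the beta-actin gene often used as a reference and chosen here after its values were seen, fell by 1.32 (SE 0.345, edgeR adjusted p = 0.0489). Under 3 other scalings its log2 fold change ran from -1.495 to -1.325. Shifts that small could not turn the sign, so the kept sign is no support. Levels of Actb were 3591, 3289 and 3464 CPM in stretched 1 to 3 and 10520, 10470 and 4802 CPM in static 1 to 3. The call did not hold with the replicate block (adjusted p = 0.0609; 2.8e-04 to 0.161 over all alternatives) or without stretched 1, stretched 2, stretched 3, static 1 or static 2 (adjusted p = 0.14, 0.153, 0.0883, 0.156 and 0.161), and without static 3 the adjusted p was 0.00404.

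The upper bound of the median of the 72 ribosome biogenesis genes was -0.948. In these 6 libraries the fall thus extended to genes of this class other than those first seen among the largest falls. The bound covers the spread over genes, which moved together (estimated correlation 0.77), and not the spread between libraries. This result describes the fall and does not explain it, and no biological explanation of the fall was tested. The highest upper bound under 3 other scalings was -0.952, while the median of all genes moved to -0.194 at most. Shifts that small could not bring a list median of -1.08 to 0. The choice among these scalings therefore does not account for the fall, and a scaling of another kind was not tested. What sets static 3 apart from the other static libraries was not resolved for these genes and stays open.

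The comparison was set against other splits of the 6 libraries into 3 and 3. The real split gave 1538 genes and was the 1 split of 10 with as many, and the highest count of another split was 0 (1379 at an unadjusted p under 0.05 in edgeR, against 4083 for the real split). That split put stretched 1, stretched 2 and static 3 together and, like the real split, is among the 4 that part all same-numbered pairs. With 10 splits the share cannot be under 0.1.

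Static 3 stood apart from static 1 and static 2, since of 6624 genes at 20 CPM or more on which static 1 and static 2 lay within 0.5 on the log2 scale, 221 were at least 2-fold higher in static 3 and 193 at least 2-fold lower. Lower depth is argued against by its total, 0.964 of the mean of static 1 and static 2. A swap with a stretched library is argued against by its Nos2 level, 0.0227 of the lowest stretched library. That rests on 1 gene, chosen after its values were seen. Slc13a3 in static 3 (137 CPM) lay in the stretched range (55.6 to 193 CPM), far below static 1 and static 2 (1719 and 1438 CPM). H2-Ab1 in static 3 (301 CPM) also lay in the stretched range (161 to 346 CPM), above static 1 and static 2 (81.6 and 63.2 CPM). More cells of the granulocyte and monocyte lineages may account for part of the higher genes. The lower of the bounds of the neutrophil and monocyte medians was 1.04, although 1 and 3 members stand in another list. Ngp lay at 5665 CPM in static 3, against 1272 and 2178 CPM in static 1 and static 2. Lyz2, which macrophages also express, lay at 21030 CPM against 17760 and 11420 CPM, so it adds little. Markers of stroma (median 0.717, interval 0.443 to 1.08, 15 of 16 genes higher), dendritic cells (0.594, 12 of 13), lung epithelium (0.54, 7 of 8), mast cells (1.19) and lymphocytes (0.909) were higher too, so that account leaves part of the higher genes open. Whether a lower share of macrophages accounts for the lower genes was not decided. The macrophage identity median had a lower bound of -0.126, but this bound covers the spread over genes within 1 library. That list holds Lyz2 and could stay level if other myeloid cells that express its genes replaced macrophages. The source of the lower genes stays open.

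Classical activation genes rose with exosomes of stretched cells, with 9 of 22 tested members higher and 13 not past the threshold (adjusted p = 5.71e-06; adjusted p = 0.627 with an estimated correlation). A choice of scaling is argued against, since 9 of the 9 called members passed under each of 3 other scalings. A larger share of neutrophils with unchanged expression is argued against too. The upper bound of the neutrophil median, with or without static 3, was 0.669, and the classical activation median was 1.43 with and 1.42 without static 3. That bound covers the spread over genes and not between libraries. Shares of other cell types were not tested. Without static 3 the medians of monocyte, mast cell and lung epithelial genes were 0.92, 0.84 and 1.14, so a change in cell make-up as a whole stays open. Endotoxin carried with the exosome preparation cannot be told apart from an effect of the exosomes. The NF-kB and interferon medians had lower bounds of at least 0.328, a rise that both explanations allow. There was no group without exosomes, and both groups received exosome preparations, so no comparison here parts endotoxin from vesicles. A response of macrophages to exosomes of stretched cells therefore stays a hypothesis.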
